A study of Homo sapiens with 8 samples.

How the data were processed

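Small RNA libraries were made from exosomes of A549 cells, per the labels' protocols: conditioned medium with exosome-depleted serum was collected after 48 hours, vesicles were precipitated with a polymer reagent and small RNA was purified on columns. The submitters' processing notes name Bowtie2 2.2.3 and the genome build GRCh38, while the read trimming, the counting tool and the miRNA annotation are not given in the sources used here. The authors deposited a single table of CPM values, that is reads of a miRNA scaled to the total miRNA reads of the library, for 2588 mature miRNA entries in 8 libraries. Its columns are named by group only, so 4 columns are scramble controls and 4 are knockdown libraries, with no link to a numbered sample; library numbers used here only name columns. No column was left unused (0 unused per-sample columns). The table calls the knockdown group by a knockout abbreviation, and the labels describe a short hairpin RNA.

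The CPM values were whole multiples of the worth of 1 read for 100% of the values (within 0.01 of a read), which gave back whole reads of each library. No pair of libraries was close enough to be 1 library deposited more than once. The lowest chi-square per miRNA between a pair was 6.84, for control libraries 1 and 3. In 10 groups of 2 entries (20 entries) all values were identical, and in each group the precursors overlap on opposite strands, so the counting did not separate strands there. Reads of such a pair cannot be assigned to 1 of them.

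The following were fixed before the data were examined: the test, the filter, the miRNA lists, the rule for named miRNAs and most alternatives. miRNAs with a mean of at least 10 CPM over the 8 libraries (344) were tested with limma 3.58.1 (R 4.3.3, empirical Bayes with a trend) on log2(CPM + 1), two-sided, with no covariate, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(CPM + 1) scale. For low miRNAs this scale can understate a change, or overstate it where some control libraries hold no read of the miRNA. Folds stated as such are ratios of mean CPM. Of 26 fixed lists, the 22 with at least 3 tested members were tested with limma's camera with an estimated correlation, a competitive test against the other miRNAs. Because the median of all tested miRNAs was above 0, camera gave a downward direction for 10 lists whose median log2 fold change was above 0, none of them called. Fry called 12 lists; it asks whether the members of a list move on balance 1 way and does not compare lists. Shares of reads and numbers of detected miRNAs were compared by exact permutation tests over the 70 label assignments, two-sided.

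miRNAs were named by rule: the 10 with the highest mean CPM, the 10 largest log2 fold changes in each direction among those called, and for each list up to 4 tested members with the smallest p. miR-10a-5p, miR-24-2-5p, miR-130b-3p, miR-196a-5p, miR-200a-5p and miR-3184-3p fall outside it and were named after their values were seen. Precursor positions came from GENCODE 29 on GRCh38, where 343 of the 344 tested miRNAs matched a precursor by name.

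As alternatives, edgeR 4.0.16 (quasi-likelihood, TMM) on the recovered reads called 152 miRNAs, 90 higher and 62 lower, of which 130 were called in the same direction by limma, and DESeq2 1.42.0 called 83 higher and 67 lower. Other pseudocounts (0.5 and 5), filters (none, 1 and 100 CPM), scalings (TMM, median centring, quantile normalization, CPM without the 10 most abundant miRNAs), prior variances, library weights, a rank test and leaving out each library were run too. Thinning to equal depth, counting identical entries once and using only control libraries 1 and 3 or 2 and 4 were added after seeing the data. The 95% interval of a ratio of pooled reads is exact and conditional on their sum; such intervals and the floor of 3 reads cover counting error only, since the reads carry no molecular identifiers here.

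The limma procedure was tested on simulated reads with the real depths. The simulated changes went up and down in equal number and left out the 10 most abundant miRNAs. Its error rates therefore do not cover a shift in the share of the abundant miRNAs, which these data show. For the knockdown against control comparison, with 339 simulated miRNAs tested, it recovered 64.1% of 39 miRNAs changed 2-fold and 87.0% of 46 changed 4-fold, and 7.14% of its calls were false, all 5 of them lower calls. Without any simulated change it called 0 of 335, and the deeper knockdown libraries alone gave a median log2 fold change of 0.09. Figures were drawn with matplotlib 3.10.9.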

Results

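The series measured the miRNAs carried by exosomes, small vesicles released by cells, from A549 cells, an established human lung carcinoma line. It compared cells in which syndecan-1 (SDC1), a cell-surface heparan sulfate proteoglycan, had been knocked down with a short hairpin RNA against cells that carried a scramble control. Each group had 4 small RNA libraries. The deposited table gave 2588 mature human miRNA entries in CPM, reads scaled to the total of the library. Of these entries 1111 were above 0 in at least 1 library. The whole reads behind the CPM values came to between 138302 and 226182 per control library and between 436840 and 605292 per knockdown library. A single read was therefore worth 4.42 to 7.23 CPM in the controls and 1.65 to 2.29 CPM in the knockdown. SDC1 mRNA was not analysed here, so the extent of the knockdown is not given. Nothing in the labels says that the libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

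The comparison asked which exosomal miRNAs differed between the SDC1 knockdown and the scramble control. The largest falls were in miR-10b-5p, known for its part in the invasion of carcinoma cells, and miR-146a-5p, an NF-kB-induced restraint on inflammatory signalling. The level of miR-10b-5p was 3685 ± 369 CPM in the controls and 96.3 ± 30.4 CPM in the knockdown (mean ± SD, n = 4 per group), 38.3-fold lower (log2 fold change -5.29, SE 0.21, limma adjusted p = 7.7e-10). The level of miR-146a-5p went from 5771 ± 1085 to 186 ± 58.3 CPM, 31.1-fold lower (log2 fold change -4.99, SE 0.23, adjusted p = 2.2e-09). The hypoxia-induced miR-210-3p fell 7.35-fold, from 2568 ± 224 to 349 ± 42.5 CPM (log2 fold change -2.88, SE 0.14), and miR-147b fell from 111 ± 33.2 to 8.05 ± 1.83 CPM (log2 fold change -3.61, SE 0.37). For each of these 4 miRNAs all 4 knockdown libraries lay below all 4 control libraries.

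The other miRNAs among the 10 largest falls were miR-1269b (log2 fold change -2.06), the epithelial miR-205-5p (-2.01), miR-215-5p (-1.99), miR-4683 (-1.87), miR-143-3p (-1.82) and miR-194-5p (-1.68). The level of miR-194-5p was 875 ± 78.4 CPM in the controls and 271 ± 12.3 CPM in the knockdown. miR-143-3p was the least abundant of them, at 32.2 ± 16.2 against 7.92 ± 2.32 CPM (adjusted p = 0.00901), and its call was lost when all libraries were thinned to equal depth (adjusted p = 0.340). On GRCh38 with GENCODE 29, MIR10B lies on chromosome 2 at 176150303 to 176150412 in an intron of HOXD3, and MIR146A lies on chromosome 5 at 160485352 to 160485450 in an exon of the noncoding MIR3142HG. MIR210 lies on chromosome 11 at 568089 to 568198 in an intron of the noncoding MIR210HG, and MIR147B lies on chromosome 15 at 45433050 to 45433129 in an exon of C15orf48. miR-10b-5p and miR-10a-5p have nearly the same sequence, so the small remainder of miR-10b-5p in the knockdown is uncertain. miR-10a-5p stood at 16620 ± 250.4 and 18335 ± 1535 CPM (log2 fold change 0.14, adjusted p = 0.332) and was called lower with median centring (-0.40) and quantile normalization (-0.28).

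**Figure D1:**
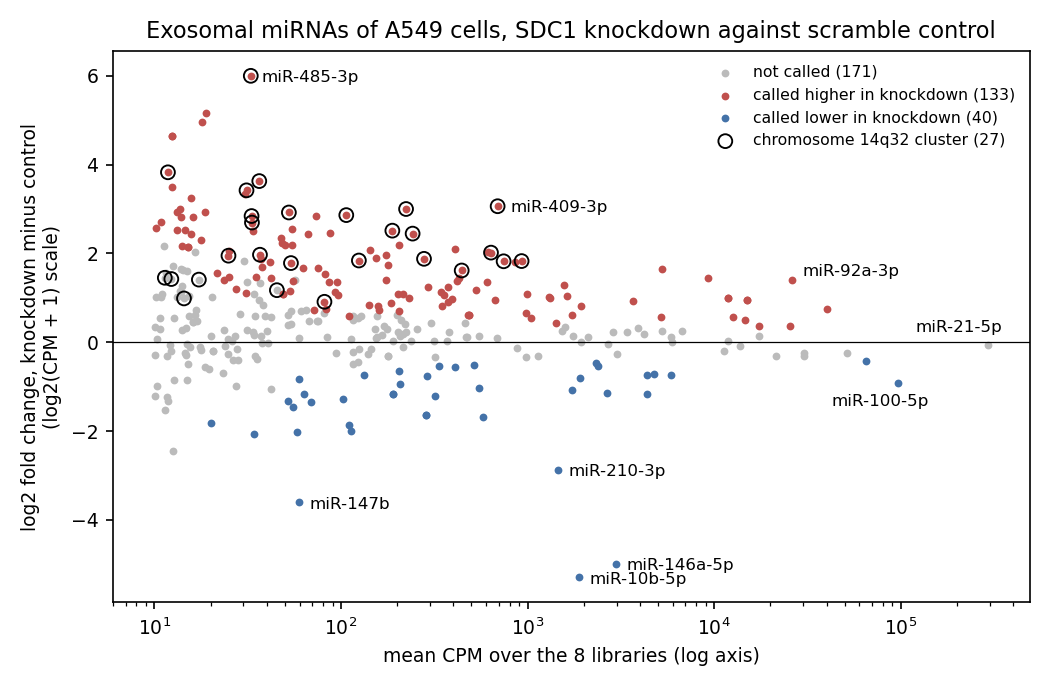
Mean level over the 8 libraries (CPM, log axis) against the log2 fold change of the knockdown over the control (log2(CPM + 1) scale) for 344 tested miRNAs. Red points were called higher (133), blue points lower (40) and grey points were not called. Open circles mark the 27 tested members of the chromosome 14q32 cluster, of which 22 were called higher and 0 lower, also 0 lower with TMM scaling.

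Among the largest rises, 5 entries had no read in any control library. Against a floor of 3 reads over the control group, equal to 4.00 CPM, miR-485-3p (65.7 ± 21.6 CPM in the knockdown) was at least 16.4-fold higher and miR-6744-5p (37.6 ± 18.2 CPM) at least 9.40-fold higher. miR-372-3p (36.0 ± 25.8 CPM), a miRNA of embryonic stem cells and germ cell tumours, was at least 8.99-fold higher. The other 2 were miR-550a-5p and miR-550b-3p, whose values were identical (24.8 ± 6.86 CPM, at least 6.19-fold higher) and whose precursors overlap on opposite strands. These folds bound only the control level and take the knockdown mean as measured. For miR-372-3p the knockdown libraries spread from 13.7 to 73.3 CPM. miR-431-3p rose from 5.99 ± 4.20 to 56.3 ± 17.7 CPM (log2 fold change 3.42, SE 0.70) and miR-485-5p from 7.65 ± 9.59 to 65.3 ± 20.9 CPM (3.63, SE 0.77). miR-29b-1-5p rose from 11.6 ± 13.4 to 49.7 ± 13.9 CPM (3.33, SE 1.01; adjusted p = 0.0149, and 0.0552 without knockdown library 3). miR-136-5p had 1 read in the controls and 46 in the knockdown, a ratio of pooled reads of 16.4 (95% counting interval 2.80 to 661). miR-130b-5p had 3 and 45, a ratio of 5.34 (1.72 to 26.9), and was not called by edgeR (adjusted p = 0.0503).

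Of the 10 most abundant miRNAs, miR-92a-3p, a member of the growth-promoting miR-17/92 cluster, moved the most on the deposited scale. It rose 2.62-fold, from 14455 ± 2552 to 37812 ± 5482 CPM (log2 fold change 1.39, SE 0.15, adjusted p = 9.1e-06). miR-100-5p fell 1.88-fold, from 126498 ± 25662 to 67291 ± 14033 CPM (log2 fold change -0.91, SE 0.18), with its call lost under quantile normalization (adjusted p = 0.348). With TMM scaling and median centring miR-100-5p moved the most (-1.28 and -1.45, against 1.03 and 0.85 for miR-92a-3p). miR-21-5p, the most abundant, held 30.0% ± 3.60 of the control reads and 28.7% ± 1.88 of the knockdown reads, a difference within the spread between libraries (log2 fold change -0.06, SE 0.14, adjusted p = 0.747). It was called lower by edgeR with TMM scaling (-0.45, adjusted p = 0.0313), by limma with median centring (-0.60, adjusted p = 0.0206) and by DESeq2. The log2 fold changes of miR-192-5p (-0.25), let-7i-5p (-0.32), miR-22-3p (-0.23) and let-7b-5p (-0.30) did not pass the limma test on the deposited scale. All 4 were called lower with TMM scaling (-0.61, -0.69, -0.60 and -0.67; adjusted p 0.00399 to 0.0150), median centring and quantile normalization. miR-320a (0.74), miR-30d-5p (0.37) and miR-30a-5p (-0.41) passed it. The calls of the first 2 were lost with TMM scaling (0.38 and 0.01). The call of miR-30a-5p was lost without any 1 of control libraries 1, 3 and 4 and knockdown libraries 2, 3 and 4 (adjusted p up to 0.102). Quantile normalization turned the sign of miR-30a-5p (0.08, adjusted p = 0.675).

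**Figure D2:**
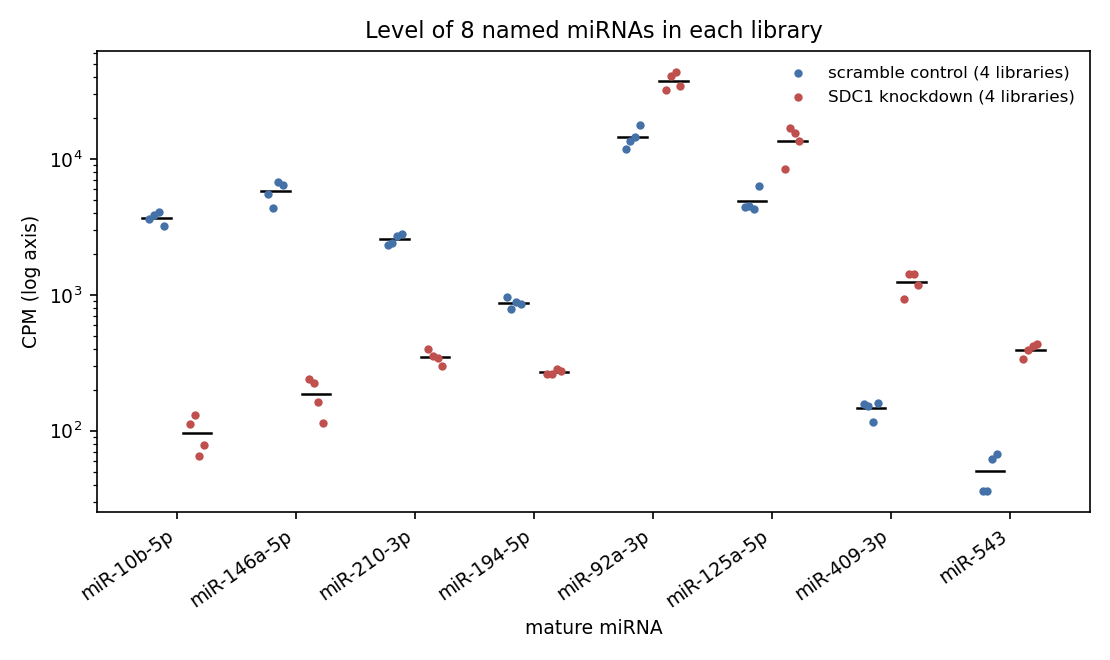
Level of 8 miRNAs in each library (CPM, log axis), 4 scramble control libraries in blue and 4 SDC1 knockdown libraries in red; black lines are the group means. The groups do not overlap for any of the 8 miRNAs. Levels are lower in the knockdown for miR-10b-5p, miR-146a-5p, miR-210-3p and miR-194-5p and higher for the other 4, in each case with TMM scaling too.

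In all, 173 of the 344 tested miRNAs were called at an adjusted p under 0.05 by limma, 133 higher and 40 lower in the knockdown (76.9% higher). Of these, 123 differed by at least 2-fold on the log2(CPM + 1) scale, not as a ratio of mean CPM, 99 higher and 24 lower. The direction split depended on the scaling. With TMM scaling 93 were called higher and 57 lower (62% higher), and the median log2 fold change of all tested miRNAs, 0.56 on the deposited scale, moved by -0.35. A core of 105 miRNAs, 69 higher and 36 lower, was called in the same direction on the deposited scale, with TMM, median centring and quantile normalization, and by edgeR and DESeq2 on the recovered reads. The core counts identical entries, such as miR-203a-3p and miR-203b-5p, separately. Thinning to equal depth was not among its settings, and it includes miR-143-3p, whose call was lost there. In 44.5% of the tested miRNAs the 2 groups did not overlap, against 2.86% by chance.

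The chromosome 14q32 cluster, an imprinted locus that carries one of the largest human miRNA groups, rose as a group. Of its 27 tested members 22 were called higher and 0 lower, and 23 were called higher when adjusted over the list alone. With TMM scaling 21 were higher and 0 lower. The median log2 fold change was 1.97 (1.62 with TMM scaling), which stayed at 1.97 with miR-485-3p set at its bound. The cluster was the only 1 of 22 tested lists called by camera with an estimated correlation (adjusted p = 0.0242). Its share of all reads went from 0.202% ± 0.0120 to 0.847% ± 0.0313 (exact permutation test, p = 0.0286, adjusted p = 0.0454). miR-409-3p rose 8.46-fold, from 146 ± 21.0 to 1235 ± 236 CPM (log2 fold change 3.06, SE 0.19), and miR-543 rose from 50.4 ± 16.8 to 396 ± 43.3 CPM (3.00, SE 0.25). miR-323a-3p rose from 25.2 ± 4.61 to 188 ± 20.7 CPM (2.86, SE 0.25) and miR-134-5p from 328 ± 49.2 to 1159 ± 103 CPM (1.82, SE 0.15). The precursor MIR543 lies on chromosome 14 at 101031987 to 101032064 in an intron of the noncoding MEG8, MIR485 at 101055419 to 101055491 outside annotated genes and MIR409 at 101065300 to 101065378 in an intron of the noncoding MEG9. The call of the list, though not the median, was lost without control library 4 (adjusted p = 0.0591, median 1.93), knockdown library 1 (0.0552, median 1.92) or knockdown library 4 (0.0506, median 2.06). It was also lost with only control libraries 1 and 3 (adjusted p = 0.146, median 2.04) or 2 and 4 (0.0597, median 2.53).

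The remaining families and clusters were not called by camera (adjusted p 0.773 to 0.932 with an estimated correlation), and their members are given as counts. In the list of miR-17/92 clusters, 7 of 16 tested members rose and 0 fell, the same counts adjusted over the list alone, with 6 and 0 by TMM scaling. miR-92a-1-5p (log2 fold change 2.47) and miR-93-5p (1.08) rose beside miR-92a-3p. The list also holds miR-92b-3p (1.01), which shares the sequence family but is encoded on chromosome 1, outside these clusters. The list's share of reads went from 2.07% ± 0.288 to 4.72% ± 0.528. In the let-7 and miR-98 family, counting both arms, 7 of 15 members rose and 0 fell on the deposited scale and over the list alone. With TMM scaling 6 rose and 3 fell. The 3p arms let-7e-3p (2.54), let-7a-3p (2.08) and let-7d-3p (1.89) were among these rises. The 3 falls with TMM scaling were all 5p arms, among them let-7i-5p (-0.69) and let-7b-5p (-0.67). The 5p arm let-7e-5p rose with that scaling (0.58). Of the miR-221 and miR-222 cluster 2 of 4 rose, miR-221-5p (2.03) and miR-222-3p (1.30), while miR-221-3p was at 0.11 (adjusted p = 0.698).

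Several families moved both ways. Of 7 tested miR-181 members 3 fell, miR-181c-5p (log2 fold change -1.45), miR-181d-5p (-1.02) and miR-181a-5p (-0.80), and 1 rose, miR-181a-2-3p (2.44). With TMM scaling 4 fell. In the miR-10, miR-99, miR-100 and miR-125 families 6 of 12 rose and 2 fell (3 fell with TMM scaling and over the list alone). miR-125a-5p rose from 4874 ± 964 to 13627 ± 3695 CPM (1.45, SE 0.20), and miR-99b-3p (1.82) and miR-125b-1-3p (1.24) rose with it, against the falls of miR-10b-5p and miR-100-5p. In the miR-23/24/27 clusters 4 of 10 rose, among them miR-23b-5p (2.24), miR-27b-5p (1.98) and miR-23b-3p (1.13), and 2 fell, miR-24-2-5p and miR-27a-3p (-0.74). TMM scaling gave 3 each way. The miR-30 family had 3 higher and 2 lower of 9 (4 higher over the list alone, 1 higher and 2 lower with TMM scaling), with miR-30c-2-3p at 1.40 and miR-30b-5p at -1.22. The miR-148, miR-152, miR-130 and miR-301 families had 2 higher and 1 lower of 8, with miR-148b-3p at 0.99 and miR-152-3p at -0.50. miR-130b-3p was called lower too with median centring and quantile normalization. The call of miR-152-3p was lost in 9 of 27 alternatives (adjusted p up to 0.0938). These included leaving out control library 1 or 4 or knockdown library 1, 2 or 3 (adjusted p up to 0.0708).

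The miR-15, miR-16, miR-195, miR-497, miR-424 and miR-503 family had 2 of 5 members higher, miR-15a-5p (2.44) and miR-16-2-3p (1.07), and the miR-29 family had 1 of 4 higher, miR-29b-1-5p. In the latter family miR-29b-3p was called lower with median centring (-0.76, adjusted p = 0.0281) and quantile normalization (-0.68, adjusted p = 0.0466), by edgeR and by DESeq2, and miR-29a-3p higher with quantile normalization (0.37, adjusted p = 0.0474). The call of miR-15a-5p was lost with quantile normalization (adjusted p = 0.0518), without the 10 most abundant miRNAs (0.0594), after thinning to equal depth and by DESeq2, and that of miR-16-2-3p with median centring (0.0674). Of the 4 tested miR-34 and miR-449 members, miR-34c-3p fell (-0.93) and miR-34c-5p rose (0.73). The rise of miR-34c-5p was lost in 16 of 27 alternatives, among them TMM scaling (0.37), edgeR and DESeq2. It was 0.45 (adjusted p = 0.0726) without control library 2, which was at 65.1 CPM against 136 to 146 in the other controls, and was also lost without knockdown library 2, 3 or 4. The fall was lost without knockdown library 2 or 3 (adjusted p = 0.0581 and 0.0559). In the miR-183, miR-96 and miR-182 cluster 2 of 4 were called higher on the deposited scale, miR-183-5p (0.56) and miR-182-5p (0.37), and 0 with TMM scaling. The miR-320 family had 2 of 5 higher (1 over the list alone), miR-320a and miR-320e (1.12), and 0 with TMM scaling. The call of miR-320e was lost in 18 of 26 alternatives (adjusted p = 0.382 with quantile normalization). None of the 6 tested members of the epithelial miR-200, miR-141 and miR-429 family was called by limma on the deposited scale or with TMM scaling. edgeR and DESeq2 called miR-200c-3p lower, and so did limma with median centring (adjusted p = 0.0328) and quantile normalization (0.0443). Limma also called miR-200a-5p lower with quantile normalization (-1.01, adjusted p = 0.0493) and miR-200b-5p higher without control library 1 (2.99). The level of miR-200c-3p was 151 ± 109 and 96.2 ± 18.9 CPM (edgeR adjusted p = 0.00763), with control library 4 at 314 CPM and the other controls at 84.0 to 108 CPM. Its limma log2 fold change was -0.45, and -0.02 without that library. miR-200a-3p (352 ± 106 and 408 ± 93.1 CPM) and miR-200b-3p (200 ± 36.7 and 230 ± 51.7 CPM) passed neither test.

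**Figure D3:**
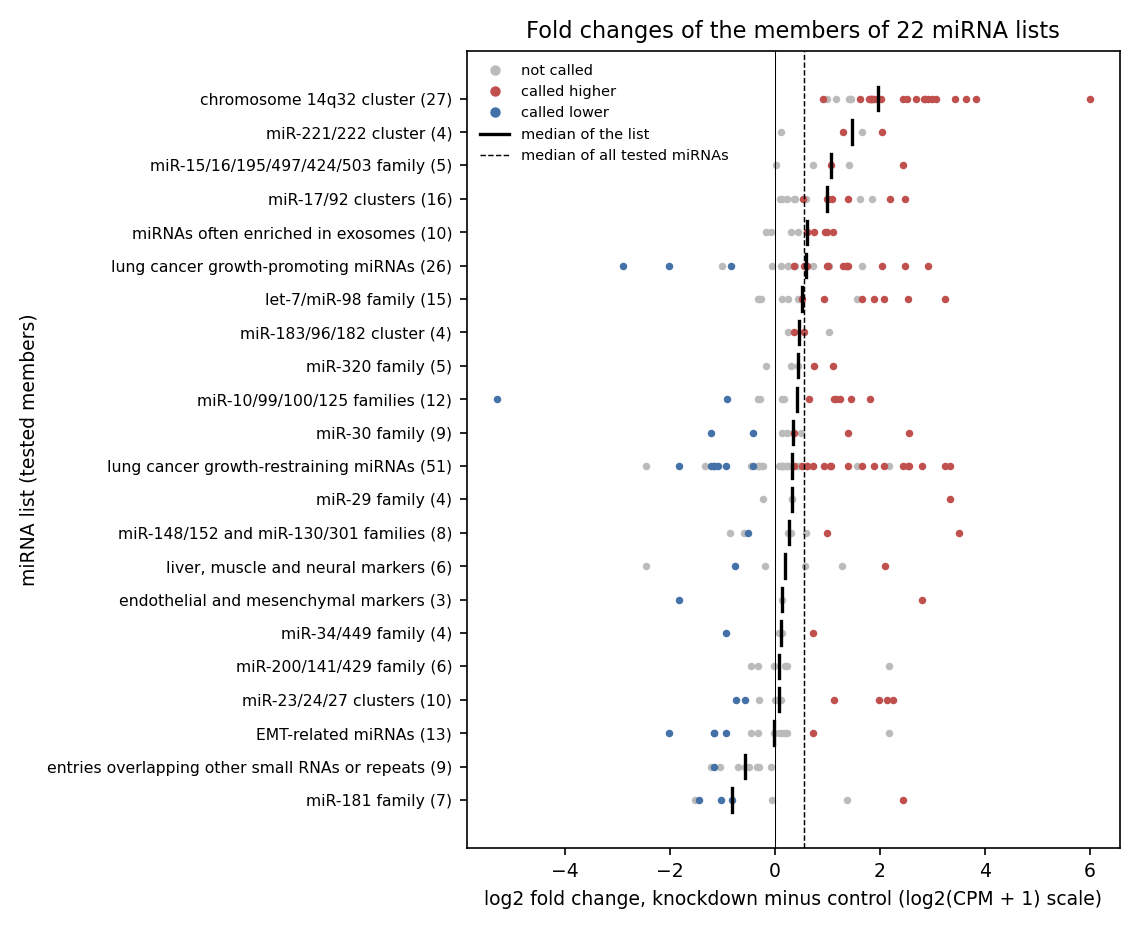
Log2 fold changes (knockdown over control, log2(CPM + 1) scale) of the tested members of 22 miRNA lists, with the number of tested members after each name. Points are miRNAs, coloured by call, black bars are list medians and the dashed line is the median of all 344 tested miRNAs (0.56). The chromosome 14q32 cluster has the highest median (1.97) and the miR-181 family the lowest (-0.80). With TMM scaling the all-miRNA median is 0.21, and the calls of miR-320a, miR-320e, miR-183-5p and miR-182-5p are lost.

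Among lists named for function, miRNAs that promote growth in lung cancer had 12 of 26 tested members higher and 3 lower (9 and 3 with TMM scaling). These lists count every arm of a named miRNA, whichever arm has the function. The rises included miR-92a-3p and the minor arms miR-21-3p (log2 fold change 1.37) and miR-221-5p. Their major arms miR-21-5p (-0.06) and miR-221-3p (0.11) were not called by limma on the deposited scale, while the major arm miR-222-3p rose (1.30). The falls were miR-210-3p, miR-205-5p and miR-196a-5p. Growth-restraining miRNAs had 18 of 51 higher and 7 lower on the deposited scale, and 12 and 10 with TMM scaling. The falls of growth-restraining miRNAs included miR-101-3p (2366 ± 407 to 1109 ± 94.2 CPM, -1.08) and miR-143-3p, and their rises the 3p arms let-7a-3p and let-7d-3p. Of 13 miRNAs that restrain epithelial-mesenchymal transition 4 fell, miR-205-5p, miR-34c-3p and the identical entries miR-203a-3p and miR-203b-5p (262 ± 62.5 to 118 ± 38.4 CPM, -1.16), and 1 rose, miR-34c-5p. With TMM scaling 4 fell and 0 rose, and by edgeR 5 fell and 0 rose. The counts on the deposited scale were the same adjusted over each list alone. None of the 3 lists was called by camera (adjusted p 0.713 to 0.895 with an estimated correlation). Both tested miRNAs reported to target SDC1 mRNA, miR-10b-5p and miR-143-3p, fell, and their list's share of reads went from 0.372% ± 0.0349 to 0.0105% ± 0.00302.

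Entries often enriched in exosomes had 6 of 10 members higher and 0 lower, also over the list alone, but 2 higher with TMM scaling. Their share of reads went from 5.01% ± 1.15 to 8.76% ± 1.12. The members that rose included miR-320a and miR-423-5p (10250 ± 2641 to 19770 ± 4875 CPM, 0.95), which shares its reads with miR-3184-3p and whose call was lost with median centring and quantile normalization. Of 9 tested entries that overlap other small RNAs or repeats only miR-6087 was called, lower (6137 ± 2522 to 2582 ± 306 CPM, -1.16), and with TMM scaling 4 were called lower. Their share was 0.684% ± 0.264 in the controls and 0.311% ± 0.0372 in the knockdown. The list was called by camera with a preset correlation (adjusted p = 0.0278) but not with an estimated one (adjusted p = 0.773). The controls differed among themselves, here and in other measures. By chi-square per miRNA, control libraries 1 and 3 (6.84) and 2 and 4 (16.1) were the closest control pairs. The other control pairs lay between 22.4 and 45.2. The 10 most abundant miRNAs held 73.2% and 73.0% of reads in control libraries 1 and 3, and 69.8% and 69.5% in 2 and 4. miR-6087 was at 4227 and 3749 CPM in control libraries 1 and 3 and at 8785 and 7787 CPM in control libraries 2 and 4, all above the highest knockdown library (2881 CPM). With only control libraries 1 and 3 the test of all miRNAs called 146 higher and 35 lower, and with only 2 and 4 it called 119 and 38.

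Markers of other cell types were few. Both tested blood cell entries, the identical miR-486-5p and miR-486-3p, were higher on the deposited scale (384 ± 62.4 to 583 ± 59.5 CPM, 0.61) and not with TMM scaling (0.25, adjusted p = 0.248). Of 3 endothelial and mesenchymal entries miR-143-3p fell and miR-126-5p rose (2.81), the latter call lost in 10 of 26 alternatives. These included median centring (adjusted p = 0.0617), quantile normalization (0.0876), CPM without the 10 most abundant miRNAs (0.0559), edgeR (0.0810) and DESeq2, and leaving out control library 1 or knockdown library 1, 2 or 3 (miR-126-5p adjusted p 0.0522 to 0.0696). Of 6 liver, muscle and neural entries the neural miR-128-3p rose from 162 ± 67.5 to 654 ± 110 CPM (2.10, SE 0.29) and miR-138-5p fell (-0.76). The muscle miR-1-3p (-2.44, adjusted p = 0.0685) was called lower with median centring and quantile normalization, without knockdown library 4, by edgeR (adjusted p = 0.00252) and by DESeq2. Its fall rests mainly on control library 1. That library held 14 reads of it, the other controls 1 to 2 and the knockdown libraries 0 to 4. No member of the chromosome 19 placental cluster or of the Xq27.3 cluster passed the filter. They held 0% and 0.000181% of the control reads and 0.000915% and 0.00118% of the knockdown reads.

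The 10 most abundant miRNAs held 71.4% ± 2.01 of the control reads and 64.7% ± 1.37 of the knockdown reads (exact permutation test, p = 0.0286, adjusted p = 0.0454). Of 27 shares compared, 17 differed between the groups. The value 0.0286 is the smallest p that 4 against 4 libraries allow, and the number called fell to 0 without any 1 library other than control library 4. The miR-10, miR-99, miR-100 and miR-125 families, which include miR-100-5p, went from 15.8% ± 2.66 to 10.8% ± 1.63 of reads, and the let-7 and miR-98 family held 8.08% ± 1.30 and 7.61% ± 1.18 (p = 0.571, exact permutation test).

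More miRNAs were detected in the knockdown, 729 ± 30.5 per library against 474 ± 34.6 in the controls (exact permutation test, p = 0.0286). Every knockdown library was deeper than every control library, so depth and group cannot be told apart for this count. With all libraries thinned to 138302 reads the means were 504.5 ± 8.18 and 434.7 ± 14.2 (p = 0.0286, exact permutation test), and at 10 CPM or more they were 351 ± 9.60 and 311 ± 25.3 (p = 0.0857, exact permutation test). Correlations of log2 CPM across tested miRNAs, which are not independent replicates, had a median of 0.978 between knockdown libraries, 0.931 between control libraries and 0.888 between a control and a knockdown library.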

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

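The tests of thinned libraries, of identical entries and of arm ratios named here were chosen only after the results were seen, as was the bound for the surplus with TMM scaling; the runs with TMM scaling and the test of other splits were planned.

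The surplus of higher over lower calls (133 against 40) was the first pattern weighed. The 35 splits of the 8 libraries into 4 and 4 were compared. Only 1, the real one, gave as many called miRNAs (173, the highest other split 0), so the calls followed the group labels. The other splits mix knockdown and control libraries, so any group difference widens their spread and leaves few calls. The test therefore cannot tell the knockdown from another difference between the groups, and it counts calls in both directions rather than the surplus. Thinning all libraries to equal depth left 73.9% of the calls higher, which argues against depth as the whole cause. With TMM scaling 62% were higher, with quantile normalization 54.4% and with median centring 50.3%. Scaling to the total in libraries led by a few miRNAs may therefore account for part or all of the surplus. The last 2 settings force the libraries to a shared distribution or median, so they cannot show how much. A true shift of many miRNAs with the knockdown stays open, because no spiked-in reference was used here.

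The rise of the chromosome 14q32 cluster was the second. Its median log2 fold change was 2.33 after thinning (adjusted p = 0.0305) and 1.62 with TMM scaling (adjusted p = 0.0446), against 1.97 on the deposited scale, and over all alternatives with an estimated correlation the adjusted p ranged from 0.0153 to 0.146. Depth and scaling are therefore unlikely as the whole cause, and 0% of the tested members shared identical values with another entry. As a hypothesis, the locus may be more active, or its miRNAs more often exported, in the knockdown cells. Whether that follows from the loss of SDC1 or from a difference between the 2 cell populations that arose by selection was not tested, since the series has 1 hairpin.

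The shift between arms of the same precursor, described under other observations, was the third. Among 18 precursors whose minor arm had at least 100 CPM, the median change of the log2 ratio of minor to major arm was 0.68 after thinning to equal depth (exact permutation test, p = 0.0286), which argues against low counts in the shallower controls as its cause. The measure used first, the median ratio within each library, changed by 0.39 in the same libraries (exact permutation test, p = 0.171), with control library 2 (-2.30) slightly above all 4 knockdown libraries (the highest also at -2.30), and the change per precursor was adopted after that. Scaling cannot produce a change of a ratio within 1 library. A difference in ligation, size selection or RNA degradation between the groups stays open, and so may a difference in the export of minor arms.

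Single libraries stood apart in 13 of 258 groups of 4 values, in all about the 1 in 20 that chance gives. Control library 4 held more of them than any other library, each time above the other controls, and related miRNAs are not independent groups. In control library 4, miR-320b was at 665 CPM (283 to 340 in the others), miR-200c-3p at 314 CPM (84.0 to 108), miR-181c-5p at 105 CPM (70.7 to 76.3), miR-320e at 43.1 CPM (13.3 to 14.5) and miR-125a-5p at 6315 CPM (4289 to 4490). In control library 2, miR-34c-5p was at 65.1 CPM (136 to 146), and 0.000723% of reads fell in the Xq27.3 cluster against 0% in the other controls. In control library 1, miR-7-5p was at 969 CPM (1083 to 1090) and miR-130b-5p at 13.5 CPM against 0, and in control library 3 miR-136-5p was at 4.42 CPM, 1 read, against 0. In knockdown library 3, miR-29b-1-5p was at 70.5 CPM (41.7 to 43.5) and miR-23b-3p at 536 CPM (443 to 458), and in knockdown library 4 the entries often enriched in exosomes held 7.10% of reads (9.15 to 9.41%). The entries under the filter, outside every test, held 0.174% of the knockdown reads, above the 0.0987 to 0.133% of the control libraries.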

How the results depend on the processing

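The runs on thinned libraries, on identical entries counted once and on control libraries 1 and 3 or 2 and 4 were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate numbers. The count of called miRNAs stayed within 1.5 times 173 in 26 of 28 alternatives; it was 101 (70 higher) with a filter of 100 CPM, where fewer miRNAs were tested, and 0 by the exact Wilcoxon rank test (0 higher, 0 lower; 153 at an unadjusted p under 0.05), whose smallest p of 0.0286 cannot pass the adjustment. Median centring gave 74 higher and 73 lower, quantile normalization 81 and 68, DESeq2 83 and 67, edgeR 62 lower, CPM without the 10 most abundant miRNAs 88 higher, and thinning with TMM scaling 71 higher; the median fold change of all tested miRNAs moved down by 0.25 to 0.54 with TMM scaling, median centring, quantile normalization and CPM without the 10 most abundant miRNAs. Leaving out 1 library gave 135 to 179 calls. The number of lists called, 1 by camera, was 2 with no filter, 2 with a preset correlation, 12 by fry, 0 with only control libraries 1 and 3, 0 with only control libraries 2 and 4, and 0 to 1 with 1 library left out. The number of shares called, 17, was 0 to 17 with 1 library left out, 17 only without control library 4. The difference in detected miRNAs was 40.25 at 10 CPM or more, no longer past the threshold, and 241 to 269 with 1 library left out. Signs turned only for miR-30a-5p (0.0804 with quantile normalization), miR-182-5p (-0.176 with median centring, -0.0954 with quantile normalization, -0.00139 by edgeR, -0.0681 by DESeq2), miR-183-5p (-0.0515 with quantile normalization) and miR-30d-5p (-0.170 with median centring, -0.0605 by DESeq2) among the called miRNAs named by rule; other than for fewer miRNAs tested and the smallest p of the rank test, the cause was not tested. Depth limits the low miRNAs most: 3 reads were 13.3 to 21.7 CPM in a control library and 4.96 to 6.87 CPM in a knockdown library.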

Other observations

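The tests of arms and of clusters without overlapping precursors in this part were chosen only after the results were seen, and the miRNAs named here were picked after their values were seen. Several minor arms, the less abundant of the 2 strands of a precursor, rose beside major arms that did not pass the test on the deposited scale. miR-21-3p rose from 339 ± 39.6 to 876 ± 112 CPM (n = 4 per group; log2 fold change 1.37, SE 0.16) beside miR-21-5p at -0.06, miR-221-5p rose by 2.03 beside miR-221-3p at 0.11, and miR-27b-5p rose by 1.98 beside miR-27b-3p at -0.0048. The same held for miR-99b-3p (1.82, miR-99b-5p 0.18) and let-7d-3p (1.89, let-7d-5p 0.44). Of 62 precursors with both arms tested, 25 minor arms were called higher and 1 lower by limma, against 21 major arms higher and 10 lower. The share of minor arms called higher was close to that of all tested miRNAs (133 of 344). The log2 ratio of minor to major arm was higher in the knockdown for 45 of the 62 precursors. The median change of this ratio over the 62 precursors was 0.65 (exact permutation test over the libraries, p = 0.0286), with knockdown libraries between 0.57 and 0.74. Ratios went the other way for some, with miR-148b-3p (0.99) above miR-148b-5p (0.31) and miR-92b-3p (1.01) above miR-92b-5p (0.37).

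Several pairs of neighbouring loci moved apart or together. miR-191-5p, encoded by MIR191 on chromosome 3 (49020618 to 49020709) next to MIR425, rose from 2584 ± 588 to 7927 ± 620 CPM (log2 fold change 1.64, SE 0.16). Of the 3 entries of the MIR425 to MIR191 cluster 2 were called higher and 0 lower, and the call of miR-425-3p was lost with TMM scaling (1.45, adjusted p = 0.0866). On chromosome 19, 5 of 6 entries of the MIR99B to MIR125A cluster rose and 0 fell (51692612 to 51693339), while 2 of 3 entries of MIR181C and MIR181D (13874699 to 13875011) and 2 of 4 of the MIR24-2 to MIR23A cluster (13836287 to 13836659) fell and 0 rose. On chromosome 9, 4 of 6 entries of the MIR23B to MIR3074 cluster rose (95085208 to 95086094) and 0 fell. The median log2 fold changes of these 4 clusters (1.31, -1.45, -0.43 and 1.55) kept their signs with TMM scaling (0.95, -1.79, -0.80 and 1.19). With that scaling the cluster on chromosome 9 had 3 higher and 1 lower, with the call of miR-3074-3p lost (1.82, adjusted p = 0.0861) and miR-3074-5p called lower, and the MIR24-2 to MIR23A cluster had 3 lower. The values of miR-3074-3p are identical to those of miR-24-1-5p.

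A hypothesis tested on the same data was that changes follow the genomic clusters from which miRNAs are transcribed. Among precursors within 10 kb of each other, the pooled SD of log2 fold changes within 25 clusters was 0.82, against a median of 1.22 in 9999 random groupings (permutation p = 1e-04, the smallest they can give). Without chromosome 14 it was 0.77 in 23 clusters against 0.99 (permutation p = 0.0039), and with TMM scaling 0.79 (permutation p = 0.0046). Overlapping precursors, such as MIR423 and MIR3184, share reads, which alone brings their fold changes together. Without them and chromosome 14 the SD was 0.77 in 21 clusters against 0.98 (permutation p = 0.0101), and 0.79 with TMM scaling (permutation p = 0.0123). This is consistent with part of the exosomal changes following transcription of the clusters in the cells, which was not measured here. Across 62 precursors the 2 arms had a Spearman's rho of 0.14 (Pearson's r 0.25; permutation p = 0.27 for rho; 95% bootstrap interval of rho -0.16 to 0.43), and across the 56 outside chromosome 14 a rho of 0.03 (Pearson's r -0.06; permutation p = 0.82; interval -0.28 to 0.33); precursors are not independent replicates. The rule first set for that test read a missed threshold as evidence against the hypothesis; it was replaced after the result was seen, because so wide an interval leaves both a shared and an unshared change open.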
